A study of Homo sapiens with 6 samples.

How the data were processed

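Gene expression was measured in primary esophageal epithelial cells grown from biopsies of patients with eosinophilic esophagitis, in 3 cultures left in media and 3 cultures stimulated with IL-13 for 48 hours. The descriptions of all 3 stimulated cultures give 100 ng/mL, while the treatment protocol gives 100 ng with no volume. Per the labels' protocols, total RNA was extracted with Trizol, checked by its ratio of ribosomal RNAs, and labelled with biotin by a modified Epicentre protocol that uses random primers. The RNA was hybridized to Affymetrix arrays, 1 array per culture.

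The deposited table holds 1 intensity per probe set and array. Per the submitters' processing notes the authors used GCRMA, which corrects each probe for background by its sequence, normalizes the arrays to one another and summarises the probes of a set. Neither the version nor the options of GCRMA are stated, and the table carries no detection calls. The deposited values are on a linear scale: all are above 0, they are right-skewed, and the 6 columns have nearly the same quantiles, so no further normalization was applied in the main analysis. The number of arrays, 3 per group, limits the precision. Dim probe sets sit near the background that GCRMA leaves, and a large fold change from such a level depends on that background.

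The arrays carry 54675 probe sets, of which 62 are Affymetrix controls that were left out of the test. Genes were named with GEO's platform annotation, which can be old, and symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCh38.p14. Of the other probe sets, 41091 name 1 gene, 1801 name several and 11721 have no gene listed. Among those with 1 gene, 41037 matched a current symbol. No gene was named from a probe set with several genes. The files name no genome build, so no coordinates are given.

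Values were taken to log2 without a pseudocount. Probe sets above their array's median on at least 3 of the 6 arrays were kept, whatever the group, which left 27660. IL-13 was compared with media by limma 3.58.1 in R 4.3.3, with the biopsy as a block and empirical Bayes moderation without a trend. P-values were adjusted by Benjamini-Hochberg over the 27660 probe sets, with a threshold of 0.05, and are two-sided. Log2 changes are IL-13 minus media and are given with the standard error of the fit. Moderation draws this error towards the usual spread of all probe sets. For genes whose 3 pairs differ widely it is smaller than the error of those pairs alone. A gene was counted by a representative probe set, the one with the highest mean among probe sets that name this gene alone, from those whose ID does not end in _x_at where there is one. This gave 12560 genes.

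The pairing comes from the series' design text, by which cells of 3 biopsies were cultured and left unstimulated or stimulated. The titles number the cultures of biopsies 1 and 2 in both arms, and the culture without a number in each arm was taken by elimination as the third biopsy. The pairing was checked on the values: the deviations of paired cultures from their group means correlated at 0.83, 0.80 and 0.75 across probe sets, and those of unpaired cultures at -0.71 to 0.34. The fit without the replicate block was an alternative, and it called 1 gene higher and 0 lower, against 90 and 66 with it.

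Before the data were examined, 27 gene lists were fixed for pathways, differentiation states and other cell types that a biopsy culture could hold. A list with at least 5 tested members, 23 in all, was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists. Camera with an estimated correlation, camera on ranks and limma's fry were alternatives. With an estimated correlation camera tests on the 2 residual degrees of freedom. Few lists can then pass after adjustment over the 23 lists, so a call lost there decides little. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes.

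The text names genes by a rule that was also fixed before the data were examined. It takes the 15 genes with the largest rise and the 10 with the largest fall, among genes past the threshold that changed the same way in all 3 pairs. It takes from each list up to 4 members past the threshold with the largest change, or the 2 with the smallest p where none passes. It also takes a fixed set of IL-13 pathway, keratinocyte and other cell type genes whatever their values. Genes named outside the rule are said to be chosen after their values were seen.

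The scripts were tested on simulated data, made from the real probe sets' means and moderated spread over the 27660 probe sets and 3 pairs. Moderation narrows the widest spreads, so recovery can be overstated for probe sets whose pairs differ widely. Of 50 probe sets each, the test recovered 100% at log2 changes of 2, -2 and -1 and 98% at 1. It also made 22 false calls beside the 200 changed probe sets. These were a larger share of all its calls than the threshold on the adjusted p aims for. The share of false calls on the real arrays was not measured and may also be larger. With nothing changed the test called 0 probe sets and 0 lists. The simulated noise was independent between probe sets. The run therefore cannot show how often camera at the preset correlation calls a list of correlated genes falsely.

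The alternatives were the fit without the block, leaving out each biopsy in turn, no filter on dim probe sets, the top 25% of probe sets by mean, quantile normalization, median centring, a pseudocount at the 25th percentile, moderation with a trend and robust estimation, array weights, and representatives without _x_at and _s_at probe sets. Other thresholds were an adjusted p of 0.1, a fold of 2, and adjustment over genes. Figures were drawn with matplotlib 3.10.9.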

Results

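Transcript levels were measured on Affymetrix arrays in primary epithelial cells cultured from esophageal biopsies of patients with eosinophilic esophagitis, a chronic inflammation of the esophagus in which eosinophils enter the epithelium. Cells of 3 biopsies were each kept in media or stimulated for 48 hours with IL-13, a type 2 cytokine, at 100 ng/mL per the sample descriptions, which gave 3 arrays per group. Intensities ranged from 7.10 to 28828 over 54675 probe sets, and the array medians lay between 43.5 and 45.2. The first principal component held 64.7% of the variance and set both cultures of biopsy 1 apart from those of biopsies 2 and 3. The second held 18.8%, and along it each IL-13 culture lay below the media culture of its biopsy.

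**Figure D1:**
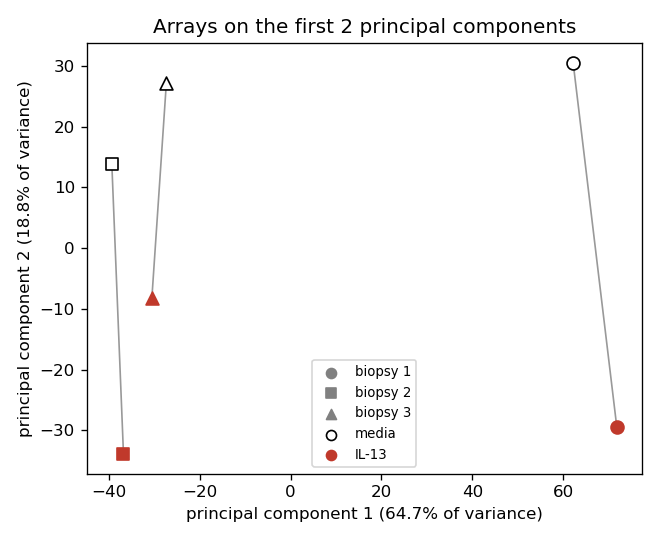
Position of the 6 arrays on the first 2 principal components of the log2 intensities, in arbitrary units, with 64.7% and 18.8% of the variance. Symbols mark the biopsy, open symbols media and filled symbols IL-13, and grey lines join the cultures of 1 biopsy. The biopsy 1 pair lies apart on the first component, and all 3 lines run the same way along the second.

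The comparison of IL-13 with media asked which transcripts of esophageal epithelial cells respond to the cytokine. The strongest rise was that of CCL26, which encodes the eosinophil chemoattractant eotaxin-3. Its geometric mean intensity was 26.9 in media and 7415 with IL-13. This is a log2 change of 8.10 ± 0.39 (SE of the fit, n = 3 pairs, adjusted p = 0.011), or 275-fold. The serine protease inhibitor SERPINB4 rose by 7.12 ± 0.37, from 45.9 to 6384, and the cadherin CDH26 by 5.63 ± 0.33, from 46.1 to 2283. The leucine-rich repeat gene LRRC31 rose by 4.66 ± 0.27, the Ras exchange factor RASGRP1 by 4.25 ± 0.50, and the calcium-activated chloride channel ANO1 by 3.80 ± 0.32. IL13RA2, the decoy receptor for IL-13, rose by 3.55 ± 0.48 (adjusted p = 0.048), DPYD, an enzyme of pyrimidine breakdown, by 3.12 ± 0.37, and the peptidase DPP4 by 3.11 ± 0.36. The remaining genes among the 15 largest rises were EML5, HLF, COL5A2, STAC, SERPINB3 and SLC9A3-AS1, with log2 changes between 2.13 and 2.82.

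The largest falls were smaller than the largest rises. The cell adhesion molecules CEACAM7 and CEACAM1 had log2 changes of -2.06 ± 0.17 and -1.87 ± 0.08 (SE of the fit, n = 3 pairs, adjusted p = 0.022 and 0.011). CYP4F3, a hydroxylase of leukotrienes and fatty acids, changed by -1.99 ± 0.27, the retinol and steroid dehydrogenase DHRS9 by -1.87 ± 0.15, and AGR2, a disulfide isomerase of secretory cells, by -1.64 ± 0.09. VSIG10L, GDPD3, DEPTOR, an inhibitor of mTOR, the surface antigen PSCA and KRT13, a keratin of mucosal suprabasal cells, changed by between -1.58 and -1.30. KRT13 fell from a mean of 9581 in media to 3880 with IL-13.

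**Figure D2:**
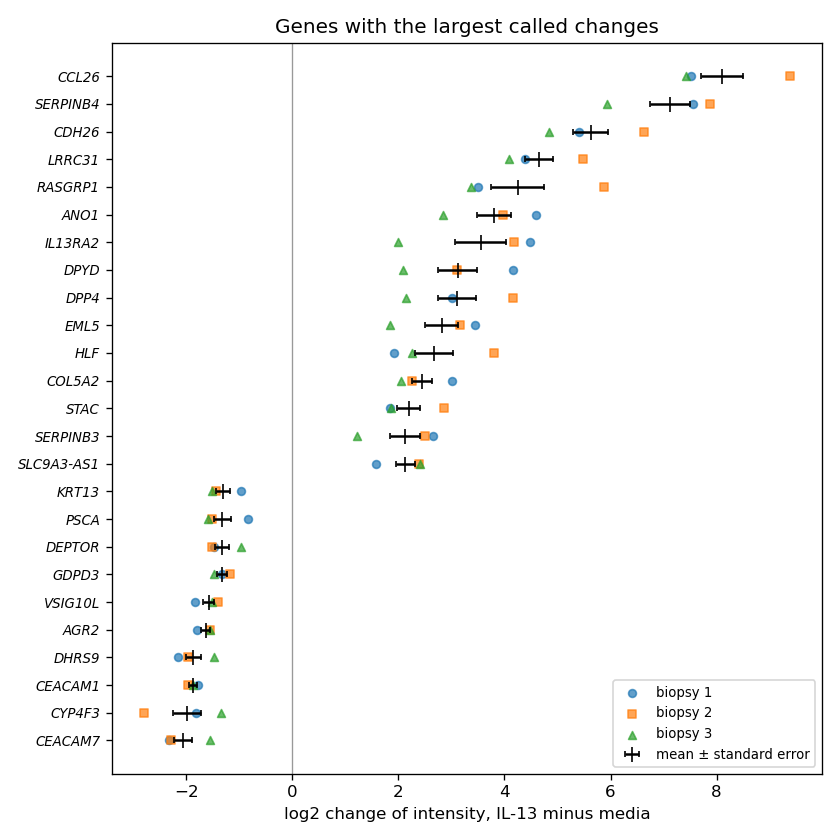
Log2 change of intensity, IL-13 minus media, of the 15 genes with the largest rise and the 10 with the largest fall past the threshold. Coloured symbols are the 3 biopsies, and black marks give the mean with the standard error of the fit. CCL26 rose by 8.10 on average and CEACAM7 changed by -2.06, with all 3 biopsies on the same side of 0 for each gene shown.

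In all, 90 genes were higher and 66 lower with IL-13 (limma, adjusted over 27660 probe sets), of 12560 tested, and 291 probe sets passed. All 156 genes changed in the same direction in the 3 pairs, and 55 of the higher and 30 of the lower genes changed at least 2-fold. Across the 27660 probe sets, which are not independent replicates, the log2 changes of biopsies 1 and 2 correlated at 0.51, those of 1 and 3 at 0.46 and those of 2 and 3 at 0.71. Of 75 called genes with more than 1 tested probe set, 74 had every probe set in the same direction. The size could differ, since the other probe set of DPYD changed by only 0.09. Those of CDH26 beside the representative changed by 5.06 and 0.13. The calls rest on the pairing: the fit with no replicate block called 1 gene higher, CCL26, and 0 lower, with 1393 probe sets at an unadjusted p under 0.05 against 5094 in the paired fit. The counts also depend on which biopsies are fitted. Higher and lower, 359 and 349 genes passed without biopsy 1, 15 and 3 without biopsy 2, and 35 and 11 without biopsy 3. All 156 genes kept their direction in each of these fits, which have fewer pairs. This follows from their shared direction in the 3 pairs and is no further support. Of the 156, all passed without biopsy 1, 17 without biopsy 2 and 32 without biopsy 3.

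Some of these folds start from a level near background. In media, 10 of the 90 higher genes, among them CCL26, LRRC31, IL13RA2, DPP4, EML5 and HLF, lay below the array median. With 18.6 added to every intensity before the logarithm, the log2 change was 7.35 for CCL26, 3.71 for LRRC31, 1.94 for EML5 and 1.95 for HLF. Without biopsy 2 it was 7.47 for CCL26 and 3.44 for RASGRP1, and without biopsy 3 it was 7.71 for SERPINB4 and 4.33 for IL13RA2. SERPINB3 and SERPINB4 are close paralogs, as are the CEACAM genes and SPRR1A and SPRR1B, and their probe sets can share signal. SLC9A3-AS1 is an antisense transcript whose probe set was taken as annotated.

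Known IL-13 and STAT6 targets of epithelium rose as a group. Of 16 tested members, 11 rose and 0 fell, or 14 and 0 adjusted over the list alone, and the median log2 change was 2.08. The filter can be passed through the IL-13 arrays alone, and without it 11 of 28 members rose, with a median of 1.01. Beside the genes above, CISH (1.85 ± 0.25) and SOCS1 (1.65 ± 0.20), feedback inhibitors of cytokine signalling, rose in this list. CAPN14, a calpain of esophageal epithelium, rose by 2.04 ± 0.18 and the protease CTSC by 1.67 ± 0.14, both named after their values were seen. POSTN, encoding the matrix protein periostin, changed by 0.63 ± 0.18 and did not pass (adjusted p = 0.16). ALOX15 was removed by the filter on dim probe sets, with mean intensities of 26.4 in media and 61.5 with IL-13. Several members were listed for what is known of esophageal epithelium under IL-13, so the list is not independent evidence of its direction. Camera gave an adjusted p of 7.6e-16 for the list, against an adjusted p = 0.53 with an estimated correlation, the highest over its alternatives for this and every other list that passed. Without the block 1 member passed, and without biopsy 2 there were 4. In all, 8 of the 23 tested lists passed, and other splits of the 6 arrays into equal groups, most of which keep the IL-13 change of 1 pair, also gave up to 8.

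The receptors and JAK-STAT components did not move together. Of 26 tested members, 3 rose (IL13RA2, CISH and SOCS1) and 0 fell, or 4 and 1 adjusted over the list alone, and camera gave an adjusted p of 0.80. The median log2 change was -0.01 and the mean 0.23, and the test pointed up. STAT6, which carries the IL-13 signal, changed by 0.17 ± 0.08, and IL4R by -0.13 ± 0.10. IL13RA1, the signalling receptor chain, was lower in 3 of 3 pairs by a log2 change of -0.62 ± 0.11 that did not pass (adjusted p = 0.070). All 4 probe sets of IL13RA1 were lower, and 1 of them, not the representative, passed (-0.71 ± 0.09, adjusted p = 0.041). The representative passed in 3 of 12 alternatives, 1 of them the fit without biopsy 1. Members past the threshold numbered 0 without biopsy 2.

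Genes of squamous differentiation were lower with IL-13. In the epidermal differentiation complex, the cluster of barrier genes in chromosome band 1q21, 2 of 27 tested members fell and 0 rose, or 15 and 0 adjusted over the list alone. These were SPRR1A (-1.29 ± 0.10) and SPRR1B (-0.91 ± 0.10), cross-linked proteins of the cornified envelope. Involucrin (IVL), another envelope protein, had means of 1826 in media and 371 with IL-13, a log2 change of -2.30 ± 0.33 that missed the threshold (adjusted p = 0.051). It passed in 9 of 12 alternatives, with adjusted p from 0.014 to 0.95. The median of the complex was -0.41 and 21 of 27 members were lower in all 3 pairs. Without the filter on dim probe sets it was -0.22 over 37 members, of which 4 fell. Among suprabasal genes outside that band, 4 of 34 fell and 0 rose, or 22 and 1 adjusted over the list alone. These were KRT13 (-1.30 ± 0.13), CEACAM5 (-0.94 ± 0.12), the epithelial transcription factor ELF3 (-0.87 ± 0.08) and CEACAM6 (-0.78 ± 0.08). KRT4, the keratin partner of KRT13, changed by -0.10 ± 0.11. The barrier genes FLG and DSG1 were removed by the filter, with mean intensities of 10.9 and 13.7 in media and 9.30 and 12.8 with IL-13.

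Camera gave adjusted p values of 1.1e-08 for the complex and 9.8e-09 for the suprabasal list, both down. Neither held with the correlation estimated from the data (adjusted p = 0.45 for each with an estimated correlation, on 2 residual degrees of freedom). Fry kept the suprabasal list alone of all lists (adjusted p = 0.0091). Counts of falling members in the complex were 9 without biopsy 1, 0 without biopsy 2 and 1 without biopsy 3, and in the suprabasal list 12, 0 and 0. Both counts were 0 without the block. Markers of columnar and glandular epithelium were lower as well, with 0 of 10 tested members higher and 1 lower, KRT7 (-0.66 ± 0.08), as adjusted over all genes and over the list alone. Their median was -0.22 and camera's adjusted p 0.0049, with an adjusted p = 0.53 with an estimated correlation. KRT7 did not pass without biopsy 2, without biopsy 3 or without the block, though its changes in biopsies 1, 2 and 3 were close, at -0.74, -0.66 and -0.58. Its other tested probe set changed by only -0.14 ± 0.10. With representatives that exclude _x_at and _s_at probe sets, 0 members of the list passed. The list's median was -0.12 without biopsy 2. Without the filter on dim probe sets the median was -0.08 over 17 members and the call was lost. As a measure of RNA quality, the log2 ratio of 3' to 5' probe sets of beta-actin was 2.18 ± 0.13 in media and 2.28 ± 0.10 with IL-13, and that of GAPDH 1.37 ± 0.08 and 1.48 ± 0.07 (SD, n = 3). Both were higher with IL-13 in 3 of 3 pairs, at the smallest p an exact two-sided sign-flip test of 3 pairs allows, 0.25. Ratios of other control transcripts were not used here.

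**Figure D3:**
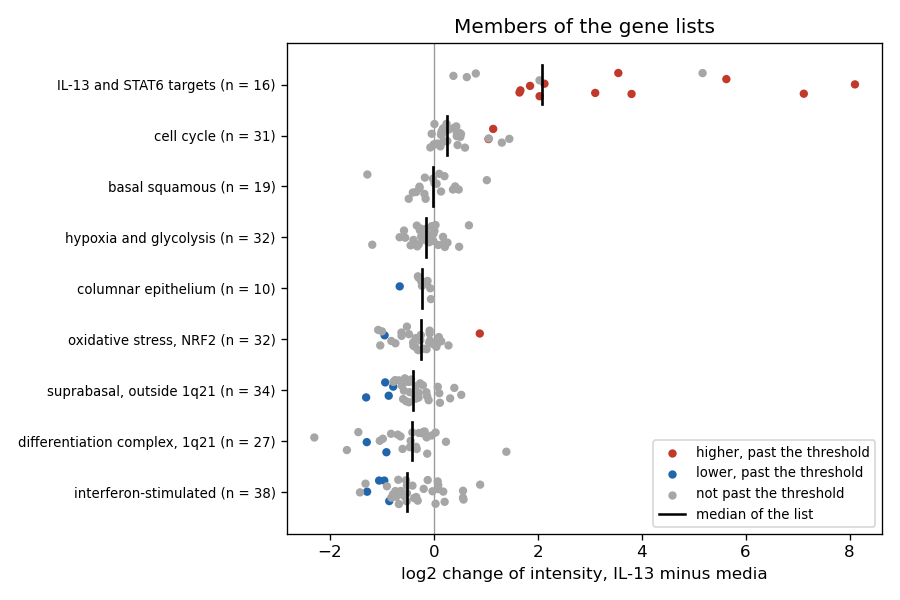
Log2 change of intensity, IL-13 minus media, of each tested member of 9 gene lists. Red and blue points passed the threshold over all genes, grey points did not, and the black bar is the median of the list. The medians were 2.08 for IL-13 and STAT6 targets, -0.41 for the differentiation complex and -0.52 for interferon-stimulated genes, and without the filter on dim probe sets 1.01, -0.22 and -0.52.

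Basal cell genes were not called as a list. Of 19 tested members 0 passed, or 3 higher and 1 lower adjusted over the list alone, with a median of -0.02 and a camera adjusted p of 1.00. The basal keratins KRT5 and KRT14 changed by -0.28 ± 0.11 and -0.48 ± 0.12, and the adhesion receptors CD44 and CDH3 by 0.48 ± 0.08 and 0.37 ± 0.08, none past the threshold. Of the 11 probe sets of CD44, 10 shared this direction. Without biopsy 1, 2 members were higher and 1 lower past the threshold.

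Cell cycle and DNA replication genes were higher as a group by a small amount. Of 31 tested members 2 rose and 0 fell, or 14 and 0 adjusted over the list alone, and 18 were higher in all 3 pairs. These were the spindle checkpoint gene MAD2L1 (1.14 ± 0.11) and RRM2, a subunit of ribonucleotide reductase (1.05 ± 0.09). The proliferation marker MKI67 changed by 0.18 ± 0.09 and did not pass (adjusted p = 0.39). The median was 0.26 and camera's adjusted p 5.5e-08, with an adjusted p = 0.53 with an estimated correlation. RRM2 changed by 1.79 when its representative excluded _x_at and _s_at probe sets. The count of rising members was 8 without biopsy 1 and 0 without biopsy 2, without biopsy 3 or without the block.

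Interferon-stimulated genes were lower. Of 38 tested members 4 fell and 0 rose, or 22 and 3 adjusted over the list alone. These were the antiviral effectors IFIT1 (-1.29 ± 0.13) and MX1 (-0.95 ± 0.13), IFI44 (-1.05 ± 0.11) and the transcription factor IRF7 (-0.86 ± 0.11). IFIT1 fell from a mean of 590.0 to 242. The media cultures of the 3 biopsies differed widely in these genes, with an SD of 1.99 for IFIT1 and 1.58 for MX1 on the log2 scale. The median was -0.52 and camera's adjusted p 1.3e-06, with an adjusted p = 0.56 with an estimated correlation. Without biopsy 1, 16 members fell and 2 rose, and 0 passed without biopsy 2, without biopsy 3 or without the block.

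Genes of oxidative stress and NRF2 were lower as a list, but the members past the threshold went both ways. Of 32 tested, catalase (CAT) rose by 0.88 ± 0.09 and metallothionein MT1H, whose probe set can also bind other metallothioneins, changed by -0.95 ± 0.10, and 1 rose and 10 fell adjusted over the list alone. The median was -0.26 and camera's adjusted p 2.8e-04, with an adjusted p = 0.53 with an estimated correlation. Without biopsy 1 the median was -0.12, and 1 member rose and 7 fell, while 0 passed without biopsy 2, without biopsy 3 or without the block. Of the 32 tested genes of hypoxia and glycolysis, 0 passed, or 1 higher and 2 lower adjusted over the list alone, with a median of -0.15 and a camera adjusted p of 0.023, or adjusted p = 0.65 with an estimated correlation. NDRG1 (-1.19 ± 0.18) and P4HA1 (-0.55 ± 0.08) had the smallest p of that list. Its call was lost without biopsy 1 (median -0.08, adjusted p = 0.071) and ranged over all alternatives from an adjusted p of 0.0074 to 0.65.

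Chemokine genes went both ways. Of 16 tested, 3 rose, CCL26 and the neutrophil chemoattractants CXCL1 (1.51 ± 0.14) and CXCL8 (1.04 ± 0.09), and 1 fell, the mucosal chemokine CXCL17 (-1.20 ± 0.10), or 4 and 4 adjusted over the list alone. Their median log2 change was -0.05, their mean 0.51, and camera, which pointed up, gave an adjusted p of 1.00. Members past the threshold numbered 5 higher and 3 lower without biopsy 1, and 1 and 0 without biopsy 2, without biopsy 3 or without the block. Among 27 epithelial cytokines and growth factors 0 passed, or 0 higher and 5 lower adjusted over the list alone, with camera's adjusted p at 0.051 and pointing down. This list was called in 5 of 15 alternatives, among them without biopsy 1 (4 members lower, adjusted p = 0.037) and without biopsy 3 (adjusted p = 0.024), over a range of adjusted p from 0.024 to 0.53. The transforming growth factor TGFB1 (-0.61 ± 0.11) and LIF (-0.50 ± 0.08) had the smallest p. TSLP, an epithelial cytokine that promotes type 2 inflammation, changed by 0.01 ± 0.15, and IL33 was removed by the filter at means of 13.8 and 11.4.

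Protease inhibitors, junction genes and matrix genes also held members of both directions. Of 28 protease inhibitors SERPINB4, SERPINB3 (2.13 ± 0.28) and SERPINB13 (0.76 ± 0.10, at the edge of the threshold with an adjusted p = 0.050) rose and WFDC2 (-0.69 ± 0.08) fell, or 6 and 7 adjusted over the list alone. Of 31 junction genes the desmosomal plakophilin PKP2 (0.98 ± 0.09) rose, and the tight junction genes CLDN8 (-1.07 ± 0.09) and TJP3 (-0.87 ± 0.08) fell, or 3 and 6 adjusted over the list alone. Of 33 matrix and remodelling genes the type V collagen chain COL5A2 (2.45 ± 0.19) and tenascin C (TNC, 1.54 ± 0.15) rose and COL12A1 (-1.07 ± 0.13) fell, or 9 and 5 adjusted over the list alone. Camera's adjusted p was 0.21, 0.10 and 0.82. The median and mean were -0.19 and 0.14 for the inhibitors, tested down, and -0.005 and 0.23 for the matrix genes, tested up. Without biopsy 1, 3 inhibitors, 3 junction genes and 9 matrix genes rose and 8, 4 and 4 fell. Without biopsy 2, 1, 0 and 0 rose, without biopsy 3, 2, 0 and 1 rose, and none of the members fell in either fit, while without the block 0 passed in either direction.

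Secretory and lipid genes changed in few members. Of 23 mucins and secretory genes AGR2 and MUC20 (from a mean of 483 to 241) fell and 0 rose, or 5 and 2 adjusted over the list alone, with a camera adjusted p of 0.071. Of 21 genes of arachidonate metabolism CYP4F3 fell and 0 rose, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.43). Among 31 genes of cholesterol and sphingolipid synthesis, 32 of the unfolded protein and stress response and 22 of antigen presentation, 0 passed over all genes or over the list alone, with camera adjusted p values of 0.056, 0.056 and 1.00. The cholesterol and sphingolipid list was called, down, in 4 of 15 alternatives, among them without biopsy 2 (adjusted p = 0.0082, range 0.0082 to 0.68). The unfolded protein list was called, down, in 6 of 15, among them without biopsy 1 (adjusted p = 0.00096, range 0.00096 to 0.72). The mucin list was called in 2 of 15, among them without biopsy 2 (adjusted p = 0.018, range 0.018 to 0.53). Without biopsy 1, mucins had 2 members higher and 4 lower and arachidonate genes 2 and 4, without biopsy 2 or 3 these were 0 and 1, and 0 and 0, and without the block 0 passed in either list. In the fit without biopsy 1, 1 unfolded protein gene and 1 antigen presentation gene fell. The members with the smallest p were SPTLC2 (-0.37 ± 0.08) and DHCR7 (-0.33 ± 0.08), VLDLR (-0.44 ± 0.08) and DDIT4 (-0.27 ± 0.08), and TAP2 (0.36 ± 0.10) and CTSS (-0.39 ± 0.11). Of 3 probe sets of TAP2, 2 shared its direction.

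Markers of other cell types gave no call in the paired fit of all arrays. Of the tested markers of fibroblasts (7), smooth muscle (6) and endothelium (5), 0 passed, and camera's adjusted p was 0.57, 1.00 and 0.87. Of markers of leukocytes (4), myeloid cells (2), eosinophils and mast cells (1) and melanocytes (3), 0 passed, and these lists were too short for a test. Adjusted over the list alone 1 gene passed among these 7 lists, CLDN5, a claudin of endothelium (2.20 ± 0.31, adjusted p = 0.051 over all genes). CLDN5 passed over all genes in 5 of 11 alternatives, with adjusted p from 0.0072, without biopsy 1, to 0.76, without the block. The fibroblast marker FAP passed with array weights. The fibroblast list had a median of -0.22 and a mean of 0.03, tested down, and the endothelial list a median of -0.01 and a mean of 0.38, tested up. Vimentin (VIM) had means of 1219 and 1025 and COL1A1, whose 4 probe sets split 2 and 2 in direction, 1151 and 909. The leukocyte gene PTPRC was removed by the filter at means of 19.7 and 19.2, and PECAM1 had means of 70.7 and 60.1. Changes in the other marker genes named by the rule were 0.87 ± 0.22 for FAP, 0.14 ± 0.10 for ACTA2, -0.41 ± 0.26 for MYLK, -0.17 ± 0.09 for CD79A, -0.18 ± 0.13 for CD48, -0.01 ± 0.09 for MS4A6A, -0.49 ± 0.55 for CD14, -0.21 ± 0.09 for GATA2, -0.18 ± 0.08 for SOX10 and -0.15 ± 0.16 for MITF. CD14 went both ways between biopsies, and without biopsy 1 its change was -1.40 and passed.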

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

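The tests of brightness-matched random lists and of an equal loss of suprabasal cells were chosen after the results they measure were seen. The list calls behind all 3 patterns below are lost with an estimated correlation. That setting has only 2 residual degrees of freedom and also lost the IL-13 and STAT6 targets. It therefore cannot decide on these calls. The lists were taken up for their shift, and the random lists draw genes independently, so their percentiles do not measure chance. They ask only whether other genes of the same brightness moved alike. The 3' to 5' ratios of beta-actin and GAPDH were higher with IL-13 in all 3 pairs, and a part of RNA quality in these patterns was not tested.

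Signal also appeared outside the named and tested probe sets. Of 3502 tested probe sets with no gene listed, 17 were higher and 7 lower with IL-13, with the largest rise at a log2 change of 3.80 and the largest fall at -0.92. Of 26953 probe sets that the filter on dim probe sets removed, 12 were higher and 9 lower in the fit of all probe sets, and 5 of the higher ones changed at least 2-fold.

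The lower interferon-stimulated genes form a pattern over 38 genes with a median log2 change of -0.52. A shift carried by 1 biopsy is argued against by the medians of the 3 pairs, of which the weakest was -0.22 and the others -0.38 and -0.78. A shift of all genes of the same brightness is argued against by 10000 brightness-matched random lists, whose medians centred on 0.0013. The list's median lay at percentile 0 of them. The values are consistent with a lower interferon response under IL-13, which is a hypothesis, and the media cultures differed widely in these genes. Interferon itself was not measured, and a difference in culture handling between the arms could not be tested.

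The lower squamous differentiation genes, 61 tested in the 2 lists together, had a median of -0.41. The weakest of the 3 pairs' medians was -0.31, which argues against 1 biopsy as the carrier. The medians of 10000 brightness-matched random lists centred on 0.0017, which argues against a general shift of bright genes. The median of the 61 genes lay at percentile 0 of them. An equal loss of all suprabasal cells, with no other change, would lower their abundant genes alike. That simple form is argued against by 14 abundant suprabasal genes, with KRT13 at -1.30 and KRT4 at -0.10. Their changes spread by 0.46 (SD on the log2 scale) beyond their standard errors (heterogeneity Q = 303 on 13 degrees of freedom). The Q takes the genes as independent and their moderated errors as known. An equal loss joined by changes of single genes would spread as well, so the test cannot decide on it. A change in part of the suprabasal programme under IL-13 stays open as a hypothesis, as does an unequal loss of cells at different stages.

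The higher cell cycle genes had a median of 0.26 over 31 genes. The weakest pair's median was 0.084, in the direction of the other pairs (0.43 and 0.32), so more than 1 biopsy carried the shift, and the list's median lay at percentile 100 of 10000 brightness-matched random lists. More dividing cells in the IL-13 cultures is a hypothesis consistent with these values, but MKI67 changed by only 0.18 and cell numbers were not used here. Differences in culture density between the arms could not be tested.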

How the results depend on the processing

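CCL26 kept its call under every alternative fit, with log2 changes of 7.35 to 8.45, while the counts moved. The paired design carries the counts: with no replicate block 1 gene was higher, 0 lower and 3 probe sets passed, and 51 of the 52 named genes past the threshold no longer passed, while the 8 list calls held. Over the fits without 1 biopsy the counts ranged from 15 to 359 genes higher, 3 to 349 lower and 31 to 1387 probe sets, highest without biopsy 1. Biopsy 1 stands apart on the first principal component, and the list counts without it were added after seeing the data, as were the levels of named genes that the filter removed. Without biopsy 2, 41 of the 52 named genes no longer passed, and without biopsy 3, 35. All 52 kept their direction in these 2 fits and without the block, which was fixed in advance. They changed the same way in all 3 pairs, and leaving out the block does not alter the log2 change of complete pairs. Without the filter on dim probe sets 112 genes were lower and 458 probe sets passed, and with the pseudocount 120 and 441. Moderation with a trend and robust estimation gave 190 higher, 181 lower and 660 probe sets, and array weights 437, 433 and 1773. An adjusted p of 0.1 gave 305, 294 and 1173, a fold of 2 gave 55, 30 and 150, and adjustment over genes alone, which tests fewer features, gave 147 and 139. Of the 8 lists, 0 passed with an estimated correlation, on 2 residual degrees of freedom, and 1 with fry. Over the alternatives their adjusted p ran from 1.5e-27 to 0.53 for IL-13 and STAT6 targets, 4.9e-10 to 0.45 for the differentiation complex and for suprabasal genes, 5.3e-13 to 0.53 for cell cycle genes, 4.9e-10 to 0.56 for interferon-stimulated genes, 1.2e-05 to 0.53 for oxidative stress and NRF2 genes and 0.0028 to 0.53 for columnar markers. Lists not called came past the threshold in some alternatives: cytokines in 5 of 15, unfolded protein genes in 6, cholesterol and sphingolipid genes in 4, mucins in 2 and protease inhibitors in 1. Except where the construction shows it (fewer samples, fewer features, another threshold), the cause was not tested. Low intensities carry no detection calls, so signal over background limits the folds of dim genes.

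Directions reversed in genes and lists that passed neither in the paired fit of all arrays nor in the fit that reversed them, and the cause was not tested. TSLP was at -0.13 with array weights and ranged from -0.20 to 0.15 without 1 biopsy. MS4A6A was at 0.0041 with quantile normalization, 0.0071 with median centring and 0.029 with array weights, and ranged from -0.095 to 0.034 without 1 biopsy. MITF ranged from -0.37 to 0.038 and CD14 from -1.40, which passed without biopsy 1, to 0.0051. Among list medians whose test direction turned, JAK-STAT components stood at -0.011 and arachidonate genes at 0.078 in the top 25% by mean. Chemokines stood at -0.052 without the block and by ranks, -0.032 with median centring and -0.13 to -0.000054 without 1 biopsy. Basal genes stood at 0.0082 with array weights, -0.018 with fry and -0.078 to 0.051 without 1 biopsy. Antigen presentation stood at -0.018 without the block, 0.033 in the top 25%, -0.019 with quantile normalization and -0.051 to 0.020 without 1 biopsy. Smooth muscle markers stood at 0.0015 without the filter, 0.00057 with quantile normalization, 0.0074 with median centring, -0.0094 with the pseudocount, 0.027 with array weights, -0.012 by ranks and -0.028 to 0.045 without 1 biopsy. Endothelial markers ranged from -0.050 to 0.023. Of the other comparisons of single named genes with their alternatives, 819 were the same, 44 now passed and 134 no longer passed, and for lists these numbers were 282, 18 and 18. Adjustment over the list alone moved 16 of 27 member counts by over 1.5 times.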

Other observations

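The gene families and the large changes that missed the threshold were chosen after the results were seen.

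Several gene families had members past the threshold, with the same signs under quantile normalization and median centring. The called CEACAM genes and MT1H were already described above. Of 6 tested CEACAM genes 4 fell and 0 rose, and CEACAM19, at 0.34 ± 0.11, did not pass. ID1 (-0.74 ± 0.08) and ID2 (-1.22 ± 0.12), inhibitors of helix-loop-helix transcription factors that BMP signalling induces, fell, while ID3 (0.65 ± 0.13) and ID4 (-0.33 ± 0.11) did not pass. Of 6 metallothioneins 5 were lower in all 3 pairs and 1, MT1H, passed, but their probe sets all end in _x_at apart from that of MT3 and can bind several of these genes. DUOX1, an oxidase that makes hydrogen peroxide at epithelial surfaces, rose by 1.75 ± 0.19, the hyaluronan synthase HAS3 by 2.00 ± 0.11 and the TGF-beta receptor TGFBR1 by 0.83 ± 0.09. The genes grouped with them by symbol alone, DUOX2 (1.15 ± 0.70), DUOXA2 (-0.16 ± 0.44), TGFBR2 (0.04 ± 0.08) and TGFBR3 (0.01 ± 0.16), did not pass.

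Some large changes missed the threshold, which at their size follows from a wide spread between biopsies. The SD of the 3 pairs taken alone, without the size of the change, does not set them apart. It was 1.41 for RASGRP1 and 1.36 for IL13RA2, which passed with log2 changes of 4.25 and 3.55. It was 0.91 for IVL, at -2.30. At least 4-fold and in the same direction in 3 pairs, 11 genes were higher and 2 lower without passing. TNFAIP6, a hyaluronan-binding protein of inflammation, had changes of 7.86, 5.81 and 1.85 in biopsies 1, 2 and 3. Their SD was 3.06 and their mean 5.17 ± 1.07 (SE of the fit, adjusted p = 0.095). LOXL4, a collagen cross-linking enzyme, had 0.69, 5.84 and 3.34, with an SD of 2.57 (mean 3.29 ± 0.90, adjusted p = 0.15). IVL had -3.14, -2.43 and -1.33, with an SD of 0.91.

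Called genes lay next to one another more often than random draws of tested genes. Of the 156 called genes 9 pairs were neighbours among tested genes, against a mean of 1.89 and a 95th percentile of 4 in 10000 draws (one-sided permutation p = 0.0001, the smallest they can give), and 8 of the 9 changed in the same direction. Shared regulation of neighbouring genes is a hypothesis, as is shared sequence within gene families, which may let 1 transcript bind the probes of its paralogs. With pairs of like-named genes left out, 3 pairs remained against a mean of 1.77 and a 95th percentile of 4 in the draws (one-sided permutation p = 0.26), which is not beyond chance. Of the 6 like-named pairs, 4 are paralogs (SERPINB4 with SERPINB3 and with SERPINB13, CEACAM5 with CEACAM6 and with CEACAM7). The other 2, PRKCQ with PRKCQ-AS1 and SLC9A3-OT1 with SLC9A3-AS1, involve antisense or overlapping transcripts of 1 locus, so the test does not concern gene families alone. These data do not separate the explanations for those pairs.

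The 6 arrays make 10 splits into equal groups, too few for a share under 0.05. The real split called 90 genes higher, 66 lower and 291 probe sets, and it alone, 1 of 10, gave counts that large, with 0 the highest of the other splits for each. For gene lists, 5 of the 10 splits gave at least the real 8 calls and the highest other split gave 8. Among the 4 splits that part all 3 pairs, the other splits gave at most 7. The 6 other splits part 1 pair only, and their fit measures the real IL-13 change of that pair, while the splits with 1 pair turned keep part of it. In both kinds the IL-13 change that the split does not follow also widens the error of responding genes. Their 0 calls are therefore not the count expected with no IL-13 effect.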
